A study of Phaeodactylum tricornutum with 9 samples.

How the data were processed

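Whole cells of the diatom Phaeodactylum tricornutum were profiled by RNA sequencing in 9 libraries, 3 labelled wild type, 3 labelled overexpression and 3 labelled knockout. Per the labels' protocols, total RNA was extracted with Trizol, libraries were built with an Illumina TruSeq RNA kit, and the instrument was an Illumina HiSeq. Groups and replicate numbers were taken from the sample titles. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

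The authors deposited 1 table of FPKM values (fragments scaled for gene length and library size), with 1 column per library. The submitters' processing notes name CASAVA 1.7, Bowtie 0.12.2 and the build mm10. That build is a mouse assembly, whereas the identifiers in the table belong to the diatom, so these notes cannot be taken to describe the alignment behind the table. The counting tool, the annotation version and any filter are not given in the sources used here. FPKM values are not counts, and no count test was used for the results reported.

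The low values of each gene were whole multiples of what 1 read is worth after 1 factor per library. Whole reads could therefore be recovered for 100% of the values above 0, within a tolerance of 0.02 reads. The same search was tested on simulated data, where it found every read in 100% of 300 simulated genes and called 0% of genes whole after noise of 0.1% was added. Recovered totals were 18049138, 18833189 and 18854201 reads for the wild type libraries, 15328873, 17382137 and 15764288 for overexpression, and 17323451, 17448738 and 15430120 for knockout. The library size implied by the deposited FPKM was 1.0004 times the median-of-ratios size in each library. The deposited scale thus sets the typical gene equal between libraries rather than the read totals. Recovered reads were used to describe depth and the spread between replicates, for genes at or near 0 reads, and in the alternatives with total-read scaling and with limma-voom. These depths cover counting error, and PCR copies of a molecule are not told apart.

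Gene names came from a table of RefSeq genes of assembly ASM15095v2. The deposited table names no build, so no coordinates are printed, and the RefSeq table was used only for names and for which loci neighbour each other. Identifiers were paired by the number in the locus name. This matched 9081 of 9275 identifiers of the form Phatr3_J and 325 of 328 of the form Phatr3_Jdraft, and 581 genes received a symbol. The pairing was checked on gene length: 20.0% of matched genes had a recovered length within 1 base of the RefSeq gene length, against a mean of 0.122% and a highest value of 0.205% over 100 shuffles. A further 2603 identifiers of the form Phatr3_EG and 412 identifiers numbered as new transcripts had no RefSeq locus and are given as the table writes them.

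Of 12804 genes, the 11279 with at least 1 FPKM in at least 3 libraries were tested. Values were transformed as log2(FPKM + 1), and all 9 libraries entered 1 limma fit with group as the only term and a trended, robust estimate of the spread. Tests were two-sided, with Benjamini-Hochberg adjustment over the tested genes of each comparison and a threshold of 0.05. Fold changes are differences on the log2(FPKM + 1) scale, which understates the change of genes with low values. The plan made before the data were examined provided for a count test if the table held counts. It held FPKM, so the limma test planned for normalised values was used, and the count tests listed as alternatives were not run. Adjusted p values for single genes below come from this limma fit.

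Themes of gene lists and search patterns were fixed at that same early stage. The reference gave symbols without product descriptions, so the patterns matched few genes, and most members were assigned by symbol afterwards, once the names and a first view of the largest changes were in hand. All members of the light-harvesting, fucosyltransferase and ribosomal protein lists matched the fixed patterns or identifiers. The lists of kinesins and myosins and of photorespiration were added at that later stage. In all, 23 lists with at least 3 tested members were tested. Patterns for transfer RNA synthetases, ribosome biogenesis, transposable elements and organelle genomes gave too few members for a test. Each list was compared with the other genes by camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 23 lists, and again with an estimated correlation. A list said below not to differ is one whose camera test did not pass, which does not show that its members were unchanged. Members were also counted with p adjusted over the list alone. The test fry, which asks whether the members move one way on balance and does not compare them with other genes, was run beside them.

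Named genes followed a rule also fixed at that stage. Per comparison, it took every fucosyltransferase locus, up to 4 members of each list with the smallest adjusted p, and the 10 largest rises and 10 largest falls among genes past the threshold with a symbol, whose values did not overlap between groups and whose mean lay at or above the median of tested genes (26.3 FPKM). It also took the 2 largest rises and 2 largest falls by the same criteria whatever the symbol. The text drops some of these genes, mainly members that did not pass and genes whose call was lost in an alternative. Other genes are named only where this is said.

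The alternatives chosen beforehand were a replicate block, a fit of only the 2 groups compared, leaving out each library in turn, a minimum absolute log2 fold change of 1, a pseudocount of 0.1, no filter on low values, and rescaling by median of ratios. Alternatives added after the data were seen were scaling by the total of recovered reads, limma-voom on the recovered reads, leaving out the loci of the RefSeq sequence that carries Phatr3_J54599, and leaving out the third libraries of both modified lines together.

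The fitting procedure was tested on simulated data with known changes, on 11291, 11291 and 11288 genes for the comparisons of knockout with wild type, overexpression with wild type and knockout with overexpression. Of genes changed 1.5-fold it recovered 3.17%, 4.48% and 4.48%, respectively. For a change of 2-fold it recovered 33.3%, 36.4% and 44.8%, and for 4-fold 78.8%, 84.4% and 78.5%. It called 4, 5 and 2 unchanged genes. Few genes were changed in these simulations, which makes the adjusted threshold stricter than in the data, so these shares do not carry over. In the data, 3030, 1428 and 3700 genes passed. Of these, 1411, 679 and 1815 had an absolute log2 change of at least 1. The work used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.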

Results

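Transcripts of Phaeodactylum tricornutum, a unicellular marine diatom that harvests light with fucoxanthin-chlorophyll proteins, were measured by RNA sequencing. The series addresses the function of an α-1,3 fucosyltransferase, an enzyme of the class that attaches fucose to glycans. Wild type cells, a line labelled overexpression and a line labelled knockout were each represented by 3 libraries of 15328873 to 18854201 recovered reads. The labels do not say which fucosyltransferase gene was altered, and the lines are called knockout and overexpression below after their labels only. Values below are deposited FPKM, given as mean ± SD with n = 3 libraries, and changes are differences of log2(FPKM + 1).

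Replicate libraries differed by more than counting noise in every pair, with a chi-square per degree of freedom of 22.7 to 82.5. The pairs with the third wild type library gave 71.1 and 82.5, and the remaining wild type pair 26.3. The third overexpression library listed 1910 genes at 0, against 1458 and 1276 in its group, and the third knockout library 1482, against 1237 and 1207. Without the third libraries of both lines, 3358 genes passed for knockout against wild type, 2248 for overexpression against wild type and 4159 for knockout against overexpression. For each gene described below as changed, the 3 values of either group lay outside the range of the other.

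Transcripts of the locus annotated as a fucosyltransferase, Phatr3_J54599, were much lower in the libraries labelled knockout. Its FPKM was 33.7, 38.8 and 33.0 in the wild type libraries, 24.6, 29.9 and 23.4 in the overexpression libraries, and 3.43, 8.42 and 5.45 in the knockout libraries. The fall against wild type was -2.48 (SE 0.253, limma adjusted p = 9.35e-05). Against overexpression it was -2.05 (limma adjusted p = 0.00022). The overexpression libraries did not have more of this transcript than wild type (log2 change -0.43, limma adjusted p = 0.289). If it is the gene that was altered, its level was not raised above wild type as that label would imply. The locus lies on a RefSeq sequence, number 10, whose 325 tested loci were lower as a block. Their median log2 change was -0.93 in knockout and -0.57 in overexpression. In overexpression the locus lies among 221 of these loci with a median of -0.95, and 74.7% of those were at or below it. Its level there can thus not be read apart from its surroundings.

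A second locus on the fucosyltransferase list, Phatr3_J46110, was higher in both modified lines. It measured 10.3 ± 2.16 FPKM in wild type, 20.4 ± 4.09 in overexpression and 18.6 ± 2.01 in knockout. The rise was 0.92 in overexpression (limma adjusted p = 0.0211) and 0.80 in knockout (limma adjusted p = 0.0193). These calls were lost when single libraries were left out. For Phatr3_J46110 knockout vs wild type, the limma adjusted p was 0.0802 without the second wild type library and 0.0689 without the third knockout library. For Phatr3_J46110 overexpression vs wild type, it was 0.0823 without the second wild type library, 0.0568 without the first overexpression library and 0.0717 without the second. The third locus, Phatr3_J46109, passed in no comparison, at 13.2 ± 1.44, 8.96 ± 1.59 and 10.4 ± 1.21 FPKM in wild type, overexpression and knockout. Of the 3 loci, 1 rose and 1 fell in knockout, with the same counts when adjusted over the list alone, and 1 rose in overexpression, with 1 higher and 1 lower when adjusted over the list alone. As a list they did not differ from other genes in knockout (camera adjusted p = 0.495) or overexpression (camera adjusted p = 0.964). The test fry, which makes no comparison with other genes, gave adjusted p = 0.0195 in knockout, with the direction down, and 0.883 in overexpression.

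**Figure D1:**
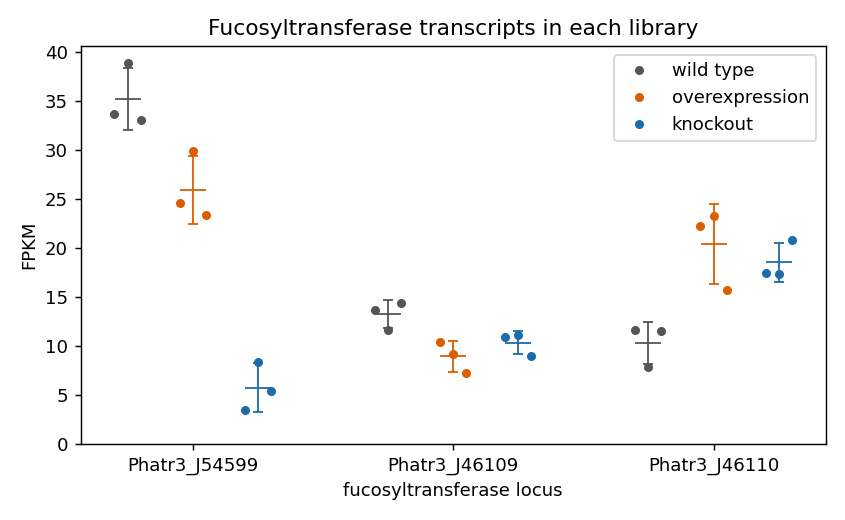
FPKM of the 3 fucosyltransferase loci in each library (points), with the group mean and SD (bars, n = 3 libraries). Phatr3_J54599 lies between 3.43 and 8.42 in the knockout libraries and between 33.0 and 38.8 in wild type, while the overexpression libraries lie below wild type.

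Compared with wild type, the libraries labelled knockout had lower transcripts of 13 of 24 genes of chlorophyll and carotenoid synthesis and of 16 of 22 light-harvesting genes. Both lists differed from other genes by camera with a preset correlation (adjusted p = 1.83e-05 each) and not with an estimated correlation (adjusted p = 0.496 and 0.526). Members of the first list were assigned after a first view of the largest changes, so its p values are not independent of them. The porphyrin gene HemE_2 (Phatr3_J19188), which encodes uroporphyrinogen decarboxylase, fell from 111 ± 55.9 to 7.18 ± 3.53 FPKM, and the antenna gene Lhcf8 (Phatr3_J22395) from 1575 ± 409 to 452 ± 92.3. The replicative helicase subunit MCM4 (Phatr3_J51412) rose from 4.01 ± 1.10 to 18.1 ± 1.46 FPKM. In all, 3030 of 11279 genes passed, 1444 higher and 1586 lower. Among the 569 tested genes with a symbol, 90 were higher and 120 lower.

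Of 24 genes of chlorophyll and carotenoid synthesis, 13 fell, 2 rose and 9 did not pass, and adjusted over the list alone 15 fell and 2 rose. The members of this list were assigned by symbol after a first view of the largest changes, so its count and list tests are not independent of them. Its median log2 change was -1.33 (camera adjusted p = 1.83e-05), with adjusted p = 0.496 with an estimated correlation. The test fry gave adjusted p = 0.00814. The third wild type library was high for several of these genes, with hemC at 316 FPKM against 151 and 129, and HemE_2 at 174 against 92.9 and 66.7. For the list chlorophyll and carotenoid synthesis, knockout vs wild type, the median was -1.07 without that library (camera adjusted p = 9.31e-05). Several fallen genes encode enzymes of the tetrapyrrole pathway. HemE_2 had a log2 change of -3.76, and hemC, porphobilinogen deaminase, one of -3.59 (SE 0.289, limma adjusted p = 1.95e-05). HemA, glutamyl-tRNA reductase, fell by 2.34 and HemD, uroporphyrinogen III synthase, fell by 2.42 on the log2 scale. HemF_2, coproporphyrinogen oxidase, went from 122 ± 17.5 to 29.7 ± 1.99 FPKM, and chlM, which methylates magnesium protoporphyrin, changed by -2.92 (SE 0.217). The members that rose, named here after their values were seen, were HemF_3, with a log2 change of 0.92, and CRTISO2, with one of 1.09. HemF_3 lies in a stretch of 67 neighbouring loci on RefSeq sequence 7 with a median of 0.45 in knockout (permutation adjusted p = 0.032). Such a stretch is the run of at least 15 loci that differed most from the other loci of its sequence, picked from these same changes. HemF_3 lies near the end of this stretch, and the other loci of the sequence had a median of -0.015. ZEP1, by its symbol of the zeaxanthin epoxidase family, went from 55.2 ± 21.3 to 6.08 ± 1.31 FPKM (log2 change -2.94, limma adjusted p = 5.44e-05).

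Of 22 tested light-harvesting genes, 16 fell, none rose and 6 did not pass, and adjusted over the list alone 17 fell. The median log2 change was -1.06 (camera adjusted p = 1.83e-05), with adjusted p = 0.526 with an estimated correlation, and fry gave adjusted p = 0.0169. Lhcf8 measured 2041 FPKM in the third wild type library, against 1403 and 1281 in the others. For the list light-harvesting proteins, knockout vs wild type, the median was -0.87 without that library (camera adjusted p = 0.000346). Lhcf14 went from 2154 ± 551 to 789 ± 234 FPKM, Lhcf1 from 1557 ± 362 to 591 ± 191 and Lhcf6 from 1300 ± 294 to 619 ± 61.8. Lhcf genes form a family of similar copies, and how reads shared between copies were counted is not given, so values of single members are uncertain. Among 6 genes of the photosystems and electron transport, 3 fell, none rose, and 4 fell when adjusted over the list alone (median -0.94, camera adjusted p = 0.0236; adjusted p = 0.496 with an estimated correlation), and fry gave adjusted p = 0.00814. Those past the threshold over all genes were OEE3, an oxygen-evolving enhancer protein (log2 change -1.97), the photosystem II subunit PsbM (-1.56) and PetJ, cytochrome c6 (-1.19). Albino3, whose homologues insert antenna proteins into thylakoid membranes, fell from 58.3 ± 19.5 to 6.76 ± 1.25 FPKM, and it lies on the lower sequence 10.

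**Figure D2:**
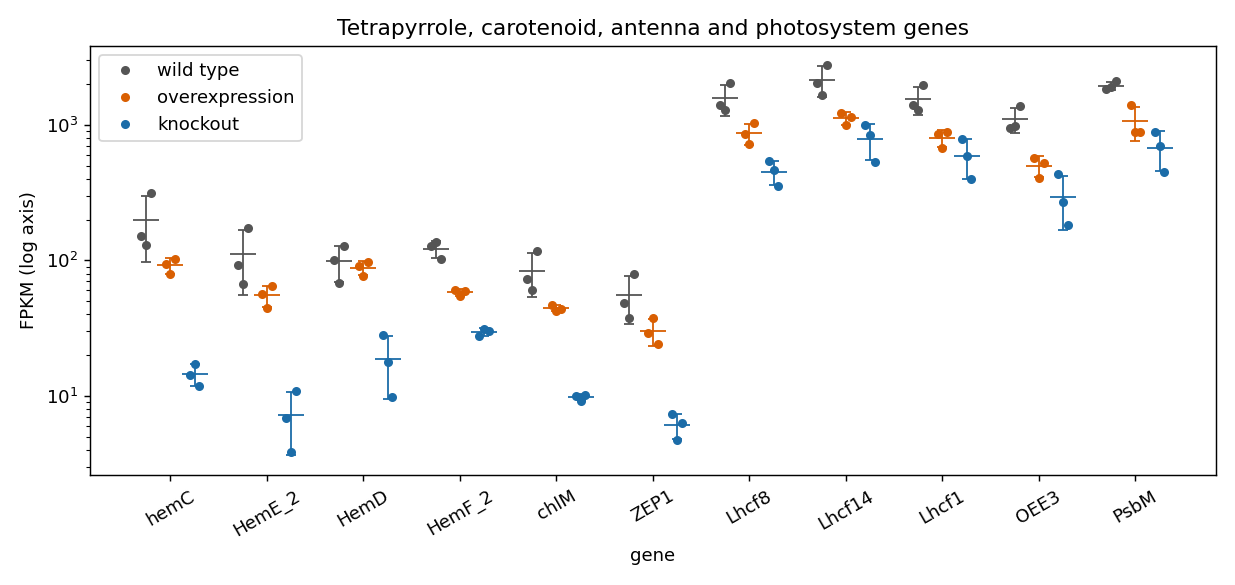
FPKM (log axis) of tetrapyrrole, carotenoid, antenna and photosystem genes in each library (points), with the group mean and SD (bars, n = 3 libraries). In each gene shown the knockout mean is the lowest, as for HemE_2 at 7.18 FPKM in knockout and 111 in wild type.

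Of 15 tested heat shock proteins and chaperones, 8 fell and 1 rose in knockout, and 10 fell and 1 rose when adjusted over the list alone. The median log2 change was -0.55 (camera adjusted p = 0.0165), with adjusted p = 0.496 with an estimated correlation, and fry gave adjusted p = 0.00657. HSP90 fell from 223 ± 29.4 to 102 ± 6.53 FPKM (limma adjusted p = 0.000561). The small heat shock protein HSP20B fell from 847 ± 284 to 236 ± 37.7 FPKM, and the Hsp70 family member HSP70F from 958 ± 221 to 478 ± 55.2.

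Genes of DNA replication and the cell cycle moved in both directions, with 21 of 64 higher, 8 lower and 35 not passing, or 24 higher and 10 lower when adjusted over the list alone. The median was 0.37, but the list test did not pass (camera adjusted p = 0.0652, or 0.496 with an estimated correlation). The test fry, which makes no comparison with other genes, gave adjusted p = 0.00836 with the direction up. In the result for the list DNA replication and cell cycle, knockout vs wild type, the camera adjusted p was 0.0308 without the second wild type library and 0.0494 without the first knockout library. PCNA, the sliding clamp of DNA polymerase, rose from 17.8 ± 0.951 to 54.5 ± 10.9 FPKM. Outside this list, the cohesin subunit SMC3 rose by 1.94 and the condensin subunit SMC2 by 1.87 on the log2 scale. Within it, the cyclin CYCD1 rose from 25.3 ± 8.03 to 82.8 ± 16.2 FPKM and CYCA/B_1 by 1.52 on the log2 scale, while the diatom-specific cyclins dsCYC5 and dsCYC7 fell, with log2 changes of -1.29 and -1.56. Motor proteins, a list formed after the data were seen, had 7 of 17 kinesins and myosins higher and none lower, or 7 higher and 1 lower when adjusted over the list alone. Its median was 0.54 (camera adjusted p = 0.00178), with adjusted p = 0.496 with an estimated correlation, and fry gave adjusted p = 0.00814. Pt-KIF2 rose by 1.80, Pt-KIF5 by 1.17 and the myosin myoA3 by 1.63.

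Of 6 genes of nucleotide sugar metabolism, 1 rose in knockout (1 adjusted over the list alone), GFA1, glutamine-fructose-6-phosphate transaminase, with a log2 change of 1.00 (limma adjusted p = 0.011). The list did not differ from other genes (median 0.12, camera adjusted p = 0.495). A mixed list of N-glycosylation and endoplasmic reticulum quality control held DER1, Spc12, DPM1, hHrd1, hPng1, GWT1 and hUba1. It does not stand for the synthesis of N-glycans. Of its 7 genes, 2 fell (2 adjusted over the list alone) and 5 did not pass, and the list test gave camera adjusted p = 0.46. Those that fell were the signal peptidase subunit Spc12 (log2 change -0.70, limma adjusted p = 0.0206) and GWT1 (-0.89, limma adjusted p = 0.022), which lies on sequence 10. For Phatr3_J13921 knockout vs wild type, which is Spc12, the limma adjusted p was 0.084 and 0.0604 without the first and the second wild type library and 0.0834 and 0.0704 without the second and the third knockout library. For Phatr3_J54588 knockout vs wild type, which is GWT1, it was 0.0776 and 0.0748 without the second and the third wild type library and 0.0947 without the second knockout library. Of 44 genes of vesicle traffic, 3 rose and 5 fell, or 1 rose and 2 fell when adjusted over the list alone (median -0.12, camera adjusted p = 0.293). Among them AP1sigma, an adaptor complex subunit, fell from 148 ± 9.03 to 82.0 ± 17.9 FPKM.

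The largest rises among genes with a symbol included RFK (Phatr3_J52223), from 85.5 ± 5.32 to 637 ± 37.0 FPKM, and ISIP3, an iron-starvation-induced protein, from 20.8 ± 3.54 to 93.9 ± 24.2. GAPDH_3, a glyceraldehyde-3-phosphate dehydrogenase, rose from 121 ± 8.45 to 377 ± 73.7 FPKM. Whatever the symbol, Phatr3_EG02511 (log2 change 4.79) and Phatr3_J14090 (4.74) rose most. Among the 2 genes that fell most by this rule was Phatr3_J15980, with a log2 change of -3.90, from 205 ± 35.7 to 12.7 ± 1.37 FPKM. The other, one of the 412 identifiers numbered as new transcripts, had 1752 to 1881 reads in the wild type libraries and 0 to 8 in the knockout libraries, a log2 change of -7.15. It had 0 to 10 reads in the overexpression libraries, where its log2 change was -6.94.

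Counts of changed genes depended on single libraries and on scaling. Leaving out the first wild type library gave 1963 genes and leaving out the second knockout library 1952. Scaling by total reads put the median of all genes at 0.14, from 0.00031, and gave 2059 higher and 1187 lower genes, in place of 1444 and 1586.

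In the libraries labelled overexpression, in which Phatr3_J54599 was not higher, 1428 genes passed against wild type, 730 higher and 698 lower. Several genes of the cell cycle list were higher. The cyclin CYCA/B_1 (Phatr3_J17135) rose from 25.5 ± 3.63 to 84.4 ± 14.4 FPKM (log2 change 1.68, limma adjusted p = 0.000797). APC8, a subunit of the anaphase-promoting complex, rose from 13.8 ± 2.35 to 42.3 ± 3.12 FPKM, and MYT1, a kinase of the type that holds back entry into mitosis, from 49.5 ± 10.2 to 106 ± 2.71. PCNA rose by 1.05 and, outside this list, SMC3 by 1.31 on the log2 scale. Of the 64 genes of DNA replication and the cell cycle, 9 rose, 2 fell and 53 did not pass, or 10 rose and 4 fell when adjusted over the list alone, and the list did not differ from other genes (median -0.01, camera adjusted p = 0.71).

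Of 22 light-harvesting genes, 5 fell and none rose in overexpression, or 9 fell when adjusted over the list alone (median -0.63, camera adjusted p = 0.0106; adjusted p = 0.874 with an estimated correlation). The test fry did not pass (adjusted p = 0.179). Their list call was lost without the third wild type library (adjusted p = 0.0614), the first overexpression library (0.0678) or the second (0.114), in the result for the list light-harvesting proteins, overexpression vs wild type. Genes of chlorophyll and carotenoid synthesis, with members assigned after a first view of the data, had 4 of 24 lower, or 7 when adjusted over the list alone. Their median was -0.28 (camera adjusted p = 0.0496), with adjusted p = 0.874 with an estimated correlation, and fry gave adjusted p = 0.268. In the result for the list chlorophyll and carotenoid synthesis, overexpression vs wild type, the median was 0.012 (camera adjusted p = 0.56) without the third wild type library. The camera adjusted p was 0.101, 0.131 and 0.0504 without the first, the second and the third overexpression library. It was 0.0597 with a pseudocount of 0.1, 0.0699 with total-read scaling, 0.072 without the third libraries of both lines and 0.0553 with only the 2 groups compared. HemF_2 fell from 122 ± 17.5 to 58.2 ± 3.18 FPKM (log2 change -1.05, limma adjusted p = 0.00171). HemF_3 fell as well, with a log2 change of -0.77, and lies in a stretch of 43 neighbouring loci on RefSeq sequence 7 with a median of -0.99. Photosystem genes did not pass as a list (2 of 6 lower, 3 adjusted over the list alone, camera adjusted p = 0.172).

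Of 15 heat shock proteins and chaperones, 2 fell and none rose in overexpression, or 8 fell and 1 rose when adjusted over the list alone. The median was -0.50 (camera adjusted p = 0.0106), with adjusted p = 0.696 with an estimated correlation, and fry gave adjusted p = 0.0204. For the list heat shock proteins and chaperones, overexpression vs wild type, the camera adjusted p was 0.0504 without the third overexpression library and 0.072 without the third libraries of both lines. The co-chaperone GrpE (Phatr3_Jdraft1725) fell from 169 ± 32.4 to 70.5 ± 10.5 FPKM. Kinesins and myosins did not differ as a list (camera adjusted p = 0.465), with 1 of 17 higher and 2 lower, or 2 higher and 2 lower when adjusted over the list alone. Neither did nucleotide sugar metabolism (0 of 6 past the threshold and 0 when adjusted over the list alone, camera adjusted p = 0.71). The mixed list of N-glycosylation and endoplasmic reticulum quality control did not differ either (1 of 7 lower and 1 adjusted over the list alone, camera adjusted p = 0.588). Its lowest member was GWT1 (log2 change -1.09), which lies on sequence 10. Of the vesicle traffic genes, 1 of 44 rose and 3 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.165), and RabX1 rose by 0.82 on the log2 scale.

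Further named changes in overexpression included METH, methionine synthase, which rose from 116 ± 13.6 to 255 ± 22.6 FPKM, and the ubiquitin ligase UPL1, which rose by 1.19 on the log2 scale. RPC11, a subunit of RNA polymerase III, fell from 61.4 ± 16.6 to 14.8 ± 6.16 FPKM, and lies on RefSeq sequence 11, whose 330 tested loci had a median of -0.36 in overexpression. The cysteine synthase CysK (Phatr3_Jdraft542) fell from 615 ± 26.1 to 218 ± 29.1 FPKM. Several large falls lay in regions that were lower as blocks. FABG, a ketoacyl-ACP reductase of fatty acid synthesis (-1.56), and IPMDH, isopropylmalate dehydrogenase (-1.63), lie on sequence 10, and the ferric reductase FRE4 (-2.43) and the myosin myoC3 (-1.34) lie in the lower stretch of sequence 7. Whatever the symbol, Phatr3_EG00141 (log2 change 4.58) and Phatr3_EG02511 (3.66) rose most. Phatr3_Jdraft1125 was listed at 0 in each of the 3 overexpression libraries and averaged 76.8 ± 9.24 FPKM in wild type.

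The number of genes past the threshold was 861, 688 and 562 without the first, the second and the third wild type library, respectively, and 826 without the second overexpression library. Scaling by total reads put the median of all genes at -0.11, from -0.045, and gave 602 higher and 833 lower genes, in place of 730 and 698.

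**Figure D3:**
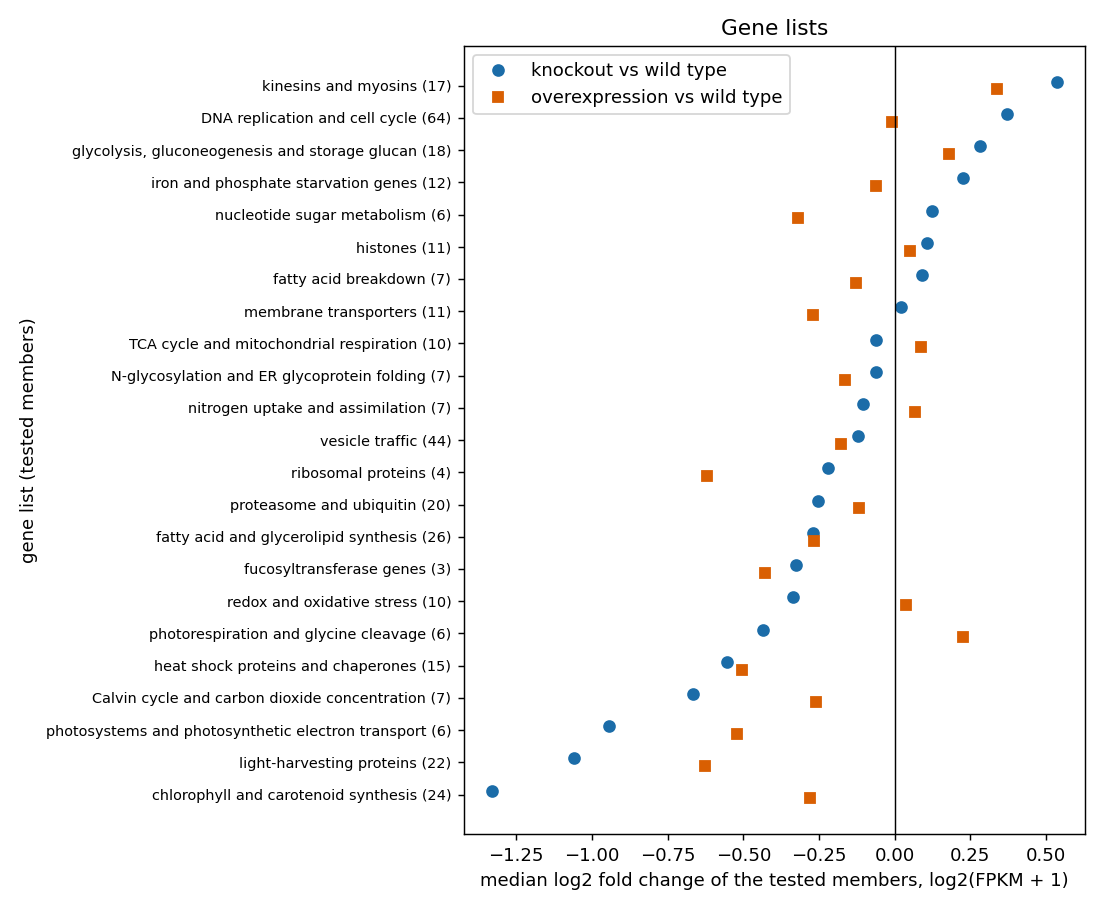
Median log2 fold change of the tested members of each gene list (number of members in brackets) against wild type, for the knockout (circles) and overexpression (squares) libraries. The lowest medians are those of chlorophyll and carotenoid synthesis in knockout (-1.33) and of light harvesting (-1.06).

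Set directly against each other, the lines labelled knockout and overexpression differed in 3700 genes, 1826 higher and 1874 lower in knockout. Of the 24 genes of chlorophyll and carotenoid synthesis, 13 were lower and 2 higher, or 14 lower and 2 higher when adjusted over the list alone. The median was -0.85 (camera adjusted p = 0.00355), with adjusted p = 0.778 with an estimated correlation, and fry gave adjusted p = 0.0371. HemE_2 measured 7.18 ± 3.53 FPKM in knockout and 55.1 ± 9.99 in overexpression (log2 difference -2.86, limma adjusted p = 0.000275). HemF_3 went the other way, with 155 ± 7.61 in knockout and 47.9 ± 7.45 in overexpression, and lies within both stretches of sequence 7, with medians against wild type of 0.45 in knockout and -0.99 in overexpression.

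Light-harvesting genes did not pass the list test between the lines (3 of 22 lower, 2 adjusted over the list alone, median -0.47, camera adjusted p = 0.0649). For the list light-harvesting proteins, knockout vs overexpression, the camera adjusted p was 0.0279 without the second overexpression library and 0.00442 without the first knockout library. Of the kinesins and myosins, 7 of 17 were higher in knockout and 1 lower, or 8 higher and 1 lower when adjusted over the list alone. Their median was 0.48 (camera adjusted p = 0.0425), with adjusted p = 0.778 with an estimated correlation, and fry gave adjusted p = 0.0327. For the list kinesins and myosins, knockout vs overexpression, the camera adjusted p was 0.082 without the first overexpression library and 0.109 without the third knockout library. It was 0.0504 with total-read scaling, 0.0565 without sequence 10, 0.05 without the third libraries of both lines and 0.0515 with only the 2 groups compared. Heat shock genes split evenly, with 3 of 15 higher and 3 lower, or 4 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.94). Among them HSP70F was lower in knockout (478 ± 55.2 against 1378 ± 104 FPKM) and HSP70B higher (12.6 ± 3.51 against 3.16 ± 0.909).

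The replication and cell cycle list did not differ as a whole (17 of 64 higher and 7 lower, 20 and 7 adjusted over the list alone, camera adjusted p = 0.305), while fry gave adjusted p = 0.0327 with the direction up. Photosystem genes (1 of 6 lower, 0 adjusted over the list alone, camera adjusted p = 0.305) and the fucosyltransferase loci (1 of 3 lower, 1 adjusted over the list alone, camera adjusted p = 0.491) did not differ as lists either, while fry gave adjusted p = 0.134 and 0.0415 for them. Of nucleotide sugar genes, 3 of 6 were higher in knockout, and 3 when adjusted over the list alone (camera adjusted p = 0.376). Among them GALE1, a UDP-galactose epimerase, was 0.83 higher in knockout on the log2 scale (limma adjusted p = 0.01). Of the mixed list of N-glycosylation and endoplasmic reticulum quality control, 1 of 7 was lower and 0 adjusted over the list alone (camera adjusted p = 0.94). Vesicle traffic genes had 6 of 44 higher and 3 lower, or 2 and 2 when adjusted over the list alone (camera adjusted p = 0.94).

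RPC11 measured 115 ± 16.6 FPKM in knockout and 14.8 ± 6.16 in overexpression. It lies with GALE1 on RefSeq sequence 11, whose 330 tested loci had a median of 0.58 in this comparison. RFK was 2.65 higher, ISIP3 2.26 higher and the chromatin remodelling subunit NURF-55 1.68 higher in knockout on the log2 scale. SHMT2, serine hydroxymethyltransferase, was lower in knockout (55.2 ± 6.37 against 165 ± 11.8 FPKM), as was the histone H3.3 (594 ± 36.7 against 1214 ± 141). Whatever the symbol, Phatr3_EG00141 (-5.90) and Phatr3_EG01403 (-4.08) were lowest in knockout relative to overexpression, and Phatr3_EG01428 measured 84.0 ± 39.4 in knockout and 0.338 ± 0.585 in overexpression. Phatr3_Jdraft1125 measured 67.1 ± 6.45 in knockout and was listed at 0 in the overexpression libraries. Scaling by total reads put the median of all genes at 0.23, from 0.032, and gave 2878 higher and 1254 lower genes, in place of 1826 and 1874.

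Changes against wild type in both lines were compared across the 11279 genes, which are not independent replicates and share the wild type libraries. Of the genes past the threshold in both comparisons, 236 were higher in both, 270 lower in both, and 62 and 64 went in opposite directions. Independent lists of these sizes would share 93.5 higher and 98.2 lower genes and 89.4 and 103 opposite ones. Pearson's r was 0.293 and Spearman's rho 0.246, and 58.2% of genes had the same sign. Simulated unchanged groups that share the 3 controls gave a mean r of 0.499, a mean rho of 0.461, 66.6% of the same sign and 0 genes called in both, over 100 draws. These draws hold no true changes, so their r, rho and sign share come from the shared controls alone. They are no baseline for the observed values, which also hold changes of each line. The covariance was 0.135 against a simulated 0.0524, a difference of 0.0826. The 3 controls cannot be split into parts of at least 2 libraries, so part of the excess of shared calls may come from the controls. Without the loci of sequence 10, 229 genes were higher in both and 160 lower in both.

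**Figure D4:**
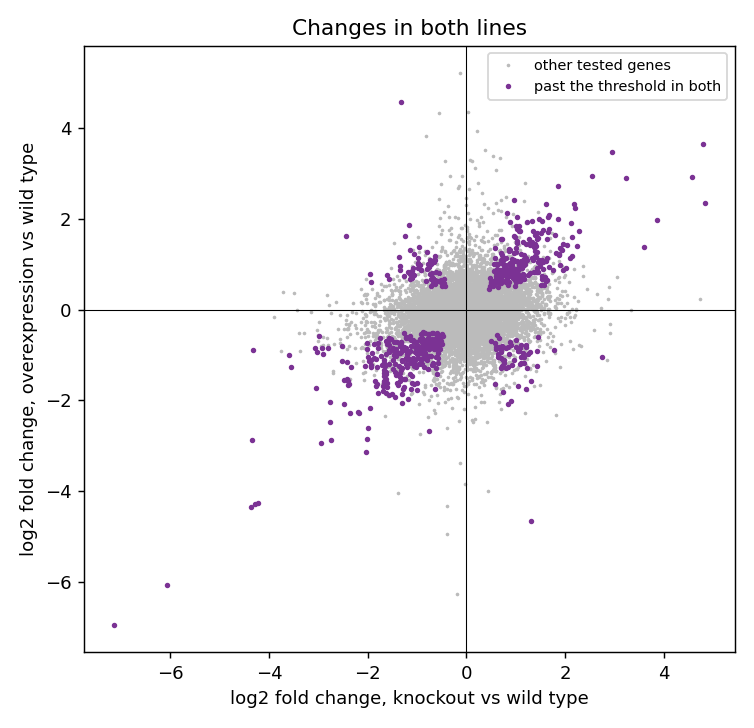
Log2 fold change of each tested gene in knockout (x axis) and overexpression (y axis) against wild type, with genes past the threshold in both comparisons in purple. Of these, 236 lie at the upper right and 270 at the lower left.

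Loci of RefSeq sequence 10, which carries Phatr3_J54599, were lower along its length in knockout. Of its 325 tested loci, 188 fell and 1 rose, which was 11.9% of all genes that fell. The median was -0.93, while 10000 random sets of loci matched on level and length had medians between -0.088 and 0.20 (permutation p = 2e-04, the smallest they can give, adjusted p = 0.0032 over the sequences). In overexpression, 124 loci fell and 3 rose, 17.8% of all falls. There 221 loci had a median of -0.95 and a run of 104 near the start of the sequence a median of -0.022, although those 104 had a median of -0.91 in knockout. Sequence 11 had a median of 0.24 in knockout and -0.36 in overexpression (adjusted p = 0.0032 each). Against wild type, sequence 32 also passed in knockout (34 loci, median 0.39, permutation adjusted p = 0.00853). Sequence 27 passed in overexpression (127 loci, median 0.10, permutation adjusted p = 0.0171). The search for stretches also passed on sequence 20 in knockout (19 loci, median 0.56, permutation adjusted p = 0.032). In overexpression it also passed on sequences 5 (17 loci, median 0.39) and 25 (35 loci, median -0.35). Random sets and permutations treat loci as independent, which neighbours are not. Their p values may thus be too small, and they do not measure the spread between libraries. Phatr3_J54599 lay 1.55 below the median of its sequence in knockout, with 4.31% of the loci at or below it. In overexpression it lay 0.52 above the median of the 221 lower loci, with 74.7% of those at or below it.

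**Figure D5:**
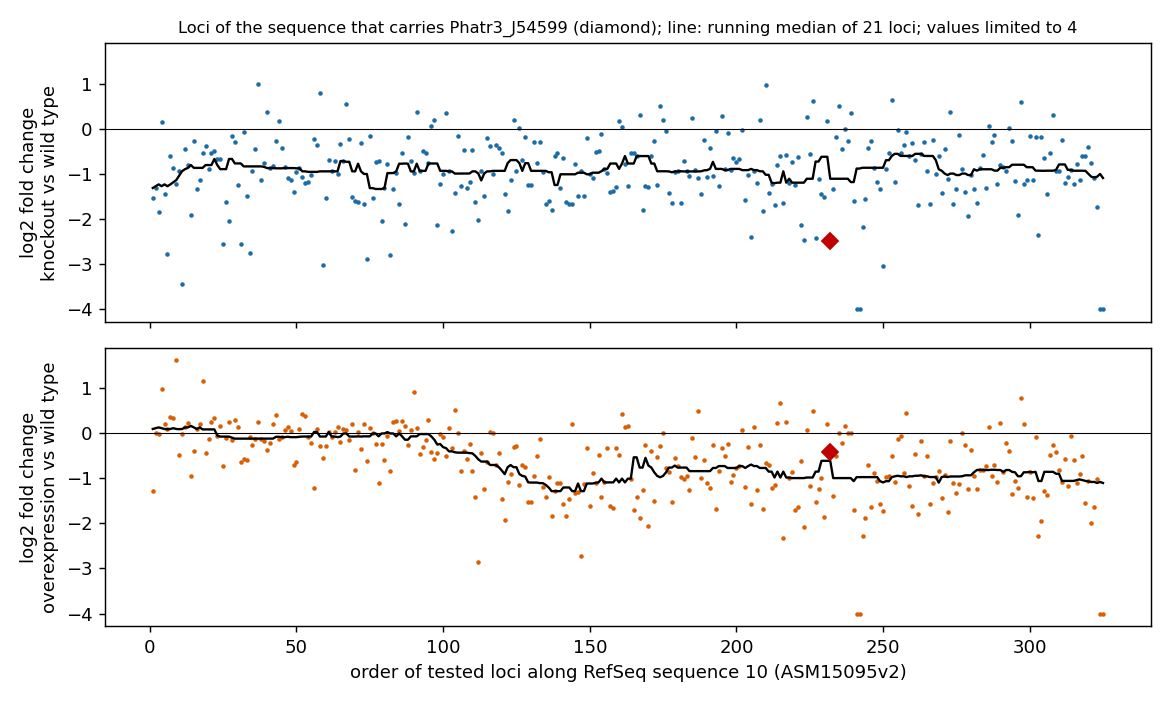
Log2 fold change of the 325 tested loci of RefSeq sequence 10 in their order along the sequence (points, limited to -4), with a running median (line) and Phatr3_J54599 (diamond), in knockout (top) and overexpression (bottom) against wild type. The knockout values centre on -0.93 along the sequence, and the overexpression values on -0.022 in a run of 104 loci near the start and -0.95 in the other 221.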

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

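Total-read scaling, limma-voom on recovered reads, leaving out sequence 10 and leaving out the third libraries of both lines were chosen only after the result was seen. With a minimum absolute log2 fold change of 1, 1411, 679 and 1815 genes passed for knockout against wild type, overexpression against wild type and knockout against overexpression, fewer by construction. Without the third libraries of both lines, 2248 genes passed for overexpression against wild type. Leaving out each library in turn gave 1952 to 2610 genes for knockout and 562 to 1741 for overexpression against wild type. Other alternatives kept these counts within 1.5 times.

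The replicate block gave 2912, 1228 and 3534 genes, of which 2763, 1152 and 3413 passed without it, and it changed no list call. Libraries of the same number had deviations correlated by -0.23 to 0.199, with 2 of 9 pairs over 0.1, and those of different numbers by -0.174 to 0.243, so the numbers do not pair the libraries.

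For Phatr3_J46110 knockout vs wild type, leaving out each library gave log2 changes of 0.63 to 0.89, and for Phatr3_J46110 overexpression vs wild type 0.75 to 1.09. With only the 2 groups compared, the latter was 0.92 and its limma adjusted p 0.05. For Phatr3_J46110 knockout vs overexpression, total-read scaling turned -0.12 (limma adjusted p = 0.718) into 0.092 (limma adjusted p = 0.758). The cause was not tested. The correlation between the changes of both lines was 0.256 without sequence 10 and 0.235 without the third libraries of both lines.

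Of 226 results for named genes, 221 passed, 151 of these kept call and direction in each alternative, 70 lost the call in at least 1 and 0 reversed. A further 97 list members that did not pass are not counted here, a choice made after 9 of them were seen to have another sign in at least 1 alternative. Of 69 list results, 16 that did not pass with either setting changed direction in at least 1 alternative. No list call held with an estimated correlation. The count tests listed as alternatives were not run, since the values are FPKM. The self-test recovered few changes under 2-fold, but few genes were changed in it, so its shares do not carry over to these data.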

Other observations

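The tests of scaling, copy number, sampling depth and position reported in this part were chosen only after the result was seen, as were the lists of photorespiration and of kinesins and myosins. Members of most gene lists were assigned once the symbols were in hand.

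Genes of glycolysis moved both ways in knockout against wild type, with 5 of 18 higher and 3 lower, or 6 and 3 when adjusted over the list alone (median 0.28, camera adjusted p = 0.249, fry adjusted p = 0.00814). TIM_2, a triose phosphate isomerase, rose from 2.16 ± 0.315 to 10.8 ± 2.61 FPKM and the pyruvate kinase PK4a from 18.1 ± 4.73 to 45.1 ± 10.8, while the aldolase Fba3 fell from 386 ± 70.3 to 201 ± 33.3. Of 7 Calvin cycle and carbon concentration genes 1 fell, and 1 when adjusted over the list alone (camera adjusted p = 0.245). This was SLC4A_1, of a family of bicarbonate transporters, which went from 24.3 ± 6.54 to 6.58 ± 2.22 FPKM. Of 11 membrane transporters 1 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.976), and the triose phosphate transporter TPT2 fell by 1.41 on the log2 scale. Of 6 photorespiration genes 1 fell, and 1 adjusted over the list alone (camera adjusted p = 0.293). None of 10 genes of the tricarboxylic acid cycle passed in the limma fit, and 0 when adjusted over the list alone (camera adjusted p = 0.849).

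Among 7 nitrogen genes 2 rose and 1 fell in knockout, with the same counts when adjusted over the list alone (median -0.10 although camera gave the direction as up, camera adjusted p = 0.549, fry adjusted p = 0.0169). Phatr3_J26029, placed on this list by its locus number, rose from 144 ± 49.3 to 1053 ± 162 FPKM, and GLNA, glutamine synthetase, fell from 379 ± 65.1 to 209 ± 14.1. Of 12 iron and phosphate starvation genes 4 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.0996, fry adjusted p = 0.00657). Fatty acid synthesis had 2 of 26 higher and 7 lower, the same when adjusted over the list alone (camera adjusted p = 0.145). For the list fatty acid and glycerolipid synthesis, knockout vs wild type, the camera adjusted p was 0.0254 without the second wild type library. ACC2, acetyl-CoA carboxylase, rose from 55.4 ± 9.03 to 125 ± 19.7 FPKM. Fatty acid breakdown had 1 of 7 lower, and 1 adjusted over the list alone (median 0.091 although camera gave the direction as down, camera adjusted p = 0.909). Redox genes had 4 of 10 lower, and 4 adjusted over the list alone (camera adjusted p = 0.15). In the result for the list redox and oxidative stress, knockout vs wild type, the camera adjusted p was 0.0494 without the first knockout library. Proteasome genes had 1 of 20 higher and 4 lower, or 1 and 7 when adjusted over the list alone (camera adjusted p = 0.235, fry adjusted p = 0.0391), among them RPN12, a proteasome subunit, from 24.3 ± 1.05 to 9.96 ± 0.832 FPKM. Ribosomal proteins had 1 of 4 lower, and 1 adjusted over the list alone (camera adjusted p = 0.705), and histones 1 of 11 higher and 1 lower, or 0 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.909).

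In overexpression against wild type, 3 of 4 ribosomal protein genes fell, and 3 when adjusted over the list alone (median -0.62, camera adjusted p = 0.088, fry adjusted p = 0.0204). Of the glycolysis genes 2 of 18 rose, and 2 when adjusted over the list alone (median 0.18, camera adjusted p = 0.088, fry adjusted p = 0.0362). For the list glycolysis, gluconeogenesis and storage glucan, overexpression vs wild type, the camera adjusted p was 0.0199 without the third wild type library, and for the list fatty acid and glycerolipid synthesis, overexpression vs wild type, it was 0.0344 without the second. Between the lines, 4 of 12 iron and phosphate starvation genes were higher in knockout and 1 lower, with the same counts when adjusted over the list alone (median 0.59, camera adjusted p = 0.0649, fry adjusted p = 0.00252). For the list iron and phosphate starvation genes, knockout vs overexpression, the camera adjusted p was 0.0441 without the second overexpression library, 0.0481 without the first knockout library and 0.0457 with no filter on low values. The test fry also passed there for photorespiration, with 2 of 6 genes lower in knockout, and 2 when adjusted over the list alone (fry adjusted p = 0.0327, camera adjusted p = 0.197). It passed too for ribosomal proteins, with 1 of 4 higher in knockout, and 1 when adjusted over the list alone (fry adjusted p = 0.0327, camera adjusted p = 0.376).

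Loci of RefSeq sequence 10 were lower as a block in knockout. On the scale of log2(FPKM + 0.1), their medians were -0.939, -0.981 and -0.974 in the 3 libraries against the wild type mean. On the scale of log2(FPKM + 1), the block lay -0.948 from the other loci with total-read scaling, and -0.944 without it. A factor per library shifts all its loci nearly alike, so this difference could hardly move and is no test of scaling. The expression level of the loci is argued against, as the lowest of the matched random sets had a median of -0.0884. A candidate explanation is a lower copy number of this sequence, for which the fall would be about equal along it, and the interquartile range of the block was 1.15 times that of other loci. DNA was not measured, so regional regulation of transcription stays open. Phatr3_J54599 had a log2 change -1.55 from the block median in knockout, but 4.31% of the loci lay at or below it, so whether its level goes beyond the block stays open.

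The 4 loci Phatr3_J46563, Phatr3_J12963, Phatr3_J13031 and Phatr3_J36647, named after their values were seen, had at most 2 reads in each knockout and overexpression library and at least 261 in each wild type library. These loci were picked for at least 30 reads in each wild type library, so a low expectation was not possible. The values still argue against sampling depth, as at least 242 reads would be expected at the wild type level and at most 2 were found. All lie on sequence 10, as 2 pairs of neighbours. The chance that 4 random loci all lie there was 2.04e-06 if they were independent. Neighbours are not, so this value is too small. The highest count of such loci in the other of the 84 sets of 6 libraries was 3. By the same bounds, at most 3 reads against at least 30, 5 loci were next to none in overexpression alone and 2 in knockout alone. None of those had a known RefSeq place. The 2 pairs lie apart, at ranks 241 and 242 and at ranks 324 and 325 of the tested loci of sequence 10. The lines may share alterations at these 2 places that the wild type libraries lack, which these data cannot test without DNA.

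In the third overexpression library, 827 genes with reads in the other overexpression libraries were listed at 0. This library had 15764288 recovered reads, more than the 15328873 of the first overexpression library, which listed fewer genes at 0. The 827 genes were 17.8 times the number expected by counting error, which, with the read totals, argues against lower depth. The ratio was 2.27 to 6.74 in the other libraries. The third overexpression library had 74 genes with 1 to 5 reads, against 125 and 185 in its group and 91 in the third knockout library. Of its genes with 5 or more expected reads, 613 were at 0, against 198 and 131 in its group. Few distinct molecules stayed open, since the variance over the mean of reads was 1.64 times the highest of the wild type and other overexpression libraries, between the bounds set for that test. No biological explanation was tested.

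Other splits of the 6 libraries of each comparison were refitted. In each comparison 1 of the 10 splits, the real one, gave as many genes past the threshold, with 3030, 1428 and 3700 genes, and the highest of the other splits gave 0. With 10 splits a share under 0.05 cannot be reached.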
